A study of Mus musculus with 6 samples.

How the data were processed

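RNA from pancreatic islets of 6 mice was measured on Affymetrix whole-genome mouse arrays, 1 array per mouse, with 3 arrays from wild-type mice (replicates 1 to 3) and 3 from hIAPP_Tg mice (replicates 4 to 6). Per the labels, all islets came from mice aged 12 weeks kept on standard chow, RNA was taken up in Trizol, and biotin-labelled cRNA was made from 150 ng of total RNA. The design text gives an age range of 10 to 12 weeks. The strain label, FVB/N-Tg(Ins2-IAPP)RFHSoel/J, is the same for both genotypes. It describes a human IAPP transgene under an insulin promoter. Groups and replicate numbers were taken from the sample titles.

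The deposited table holds log2 expression values for 45101 probe sets, normalized with RMA in the affy package per the submitters' processing notes. The versions of both are not given in the sources used here. The values ran from 2.9 to 15.1, were rounded to a step of 0.1, and had a median of 5.7 on each of the 6 arrays, so centring the arrays on their medians changed no call. For 286 of the probe sets tested the 3 values were identical within both genotypes. RMA sets the distribution of every array alike and compresses differences near the floor and near the top of the scale. An array has no read depth, and the number of arrays limits the precision here. The 64 control probe sets were left out, which left 45037 to be tested. The 3'-to-5' difference of the actin control was 1.2 to 1.3 on all arrays on the log2 scale, and that of Gapdh 0 to 0.2.

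Gene names came from the platform annotation paired with the probe sets and were looked up by Entrez number in a RefSeq gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes only. Of the probe sets tested, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here, and the named ones covered 18193 genes. The lookup changed 0 symbols and did not hold the Entrez number of 204 probe sets, whose symbols were kept. Some genes on the lists below are not analysed here.

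Each probe set was tested for a difference between genotypes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. The replicate numbers differ between the genotypes, so no pairing was used. A total of 29 gene lists were written before the data were examined. Of their 904 entries, 835 were measured. Per gene the probe set with the highest mean over all arrays stood for it. Lists with at least 5 measured members, 28 in number, were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation, with fry and with camera on ranks. The list of X- and Y-linked genes had too few measured members.

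Named genes were fixed by a rule. Iapp, Ins2, Gcg, Sst and Ppy were always named. In each direction up to 10 genes past the threshold whose genotypes did not overlap were named by size of difference. Open places went to genes not past the threshold with the smallest p, no overlap and a log2 difference of at least 0.5. In these 2 steps the probe set with the largest difference, or for open places the smallest p, stood for the gene, which need not be its brightest. Up to 2 members per direction of each list were eligible too. Predicted genes were passed over, which left out 1. Further members of the lists that the text names, Lyz2 among them, were chosen after their values were seen.

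Alternatives fixed before the data were examined were quantile normalization, median centring, 2 filters on dim probe sets, a prior with an intensity trend, a robust prior, array quality weights, an ordinary linear model test without moderation, averaging the probe sets of a gene, and leaving out each of the 6 arrays in turn. Added after seeing the data were noise within the rounding step (20 seeded draws) and the mean over the acinar markers as a covariate. The tests were tried on simulated data with 200 changed probe sets among 45037, drawn for hIAPP_Tg against wild type from the real means and spreads and rounded alike. Of simulated changes of 1 on the log2 scale 69% were recovered, and of changes of 2, 89%. Among 160 calls, 2 were false. With no change simulated, 0 probe sets passed and 6.41% had an unadjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.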

Results

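Expression was measured in isolated pancreatic islets of 6 mice, 3 wild type and 3 hIAPP_Tg, which carry the human gene for islet amyloid polypeptide (IAPP) under an insulin promoter. IAPP is co-secreted with insulin from beta cells, and its human form, unlike the mouse form, readily forms amyloid. Each array held RNA of 1 mouse, and all values are log2 RMA values as the authors deposited them, with differences given as hIAPP_Tg minus wild type. The single comparison of the design asks how islet gene expression differs between the genotypes at 12 weeks of age.

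None of the 4 mouse Iapp probe sets passed the test between genotypes. The brightest stood at 14.97 ± 0.058 in hIAPP_Tg and 14.93 ± 0.058 in wild-type islets (SD, n = 3 each; limma adjusted p = 0.908), and the others differed by -0.067 to 0. Mouse probes need not bind the human transcript, so this check of the genotype labels is void. Ins2, which encodes insulin, was at 15.1 on every array, the top value of the table, where a difference could be hidden by saturation. Glucagon (Gcg) differed by 0.033, somatostatin (Sst) by -0.10 and pancreatic polypeptide (Ppy) by 0. Their means in hIAPP_Tg islets were 14.8, 14.07 and 14.5, also near the top of the scale, where differences are compressed. None of the 3 passed the limma test. Y-linked transcripts were present in both genotypes, and Eif2s3y differed by -0.10.

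Few genes separated the genotypes past the threshold. Of the 8 named ones, 3 are on the list of macrophage markers, and Sema5a and Snhg18 are neighbours. Sema5a, a transmembrane semaphorin of axon guidance, rose from 5.23 ± 0.058 in wild-type to 9.67 ± 0.29 in hIAPP_Tg islets (SD, n = 3 each; log2 difference 4.43, SE 0.14, limma adjusted p = 0.00099). Its wild-type level lay under the array median of 5.7 and is not known to be above background, in which case the difference is a lower bound. Snhg18, a long non-coding RNA that hosts a small nucleolar RNA and lies next to Sema5a, rose 4.39-fold (7.93 ± 0.058 to 10.07 ± 0.15, limma adjusted p = 0.0034). On the macrophage list, the probe set named for lysozyme Lyz1 rose by 2.47 (SE 0.19), the pore-forming Mpeg1 by 1.57 (SE 0.078) and the receptor adaptor Tyrobp by 1.5 (SE 0.11). The Lyz1 probe set may also read the near-identical Lyz2. On none of the lists, the membrane protein gene Ms4a7 rose by 1.90 (SE 0.13) and Pla2g7, a secreted phospholipase that degrades platelet-activating factor, by 1.43 (SE 0.090). The only named gene that fell was Arntl, the core activator of the circadian clock, from 8.13 ± 0.058 to 5.97 ± 0.31 (log2 difference -2.17, SE 0.15, limma adjusted p = 0.0269). The hour at which islets were collected is not given in the sources used here.

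**Figure D1:**
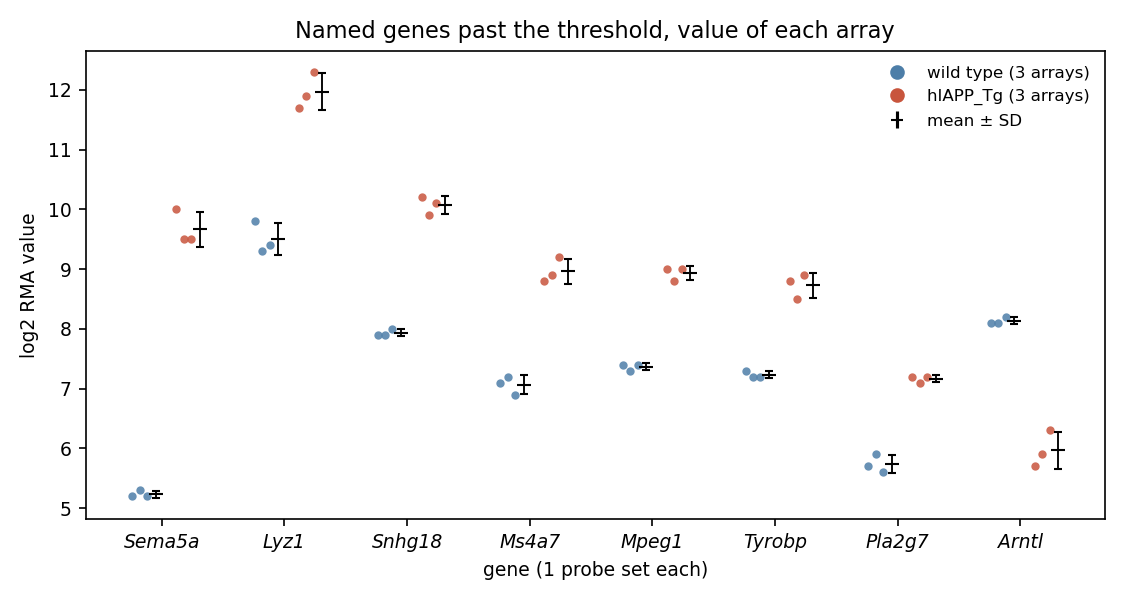
Values of single arrays (points, log2 RMA value on the vertical axis) for the 8 named genes past the threshold, 1 probe set each, with the mean and SD of 3 wild-type and 3 hIAPP_Tg arrays beside them. The genotypes do not overlap for any of the 8 genes, and Sema5a shows the widest gap, with means of 5.23 and 9.67.

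In all, 13 of 45037 probe sets passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 12 higher and 1 lower in hIAPP_Tg islets. They included 10 probe sets of the 8 named genes, 1 with several gene symbols (log2 difference 1.43) and 2 without a gene name here. Of these last, one was higher in hIAPP_Tg islets by 3.37 on the log2 scale (8.0 ± 0.10 against 4.63 ± 0.058, limma adjusted p = 0.000156), again from a level not known to be above background, and the other by 0.83. At an unadjusted p under 0.05 there were 3300 probe sets, 1719 higher and 1581 lower. That is 7.33% of those tested, while 2252 probe sets are expected by chance at this p. The simulation with no change gave 6.41%. It took the measured spread of each probe set as its true spread, so this share is no firm chance level. Neither value allows for genes that vary together. Of the 3300, 240 differed by 1.5-fold or more, 155 higher and 85 lower. The genotypes did not overlap for 6.66% of the probe sets, against 10% expected by chance for 3 against 3, with rounded values that tie counted as overlapping.

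Probe sets of a gene did not always move together. For Sema5a, 3 of 4 probe sets were higher at an unadjusted p under 0.05, with differences of 4.43, 4.13 and 1.13. The probe set with 1.13 lay near the floor, at 4.63 in hIAPP_Tg and 3.50 in wild-type islets. So did the remaining probe set, at 4.73 and 4.67, which differed by 0.067. Lyz1 had 2 probe sets past the threshold and 1 at the floor that did not differ. Its near-identical paralog Lyz2 also differed by 2.47 (limma adjusted p = 0.0555), and the probes are not certain to separate the pair. The brightest Lyz1 probe set was at 9.8, 9.3 and 9.4 on the wild-type and 11.7, 11.9 and 12.3 on the hIAPP_Tg arrays. That of Lyz2 moved in step, at 8.9, 8.4 and 8.5 against 10.8, 10.9 and 11.5. The rise can therefore not be credited to Lyz1 rather than Lyz2. The second probe set of Ms4a7 differed by 0 and that of Arntl by -0.27. With the probe sets of a gene averaged, these 4 genes still passed, with differences of 2.44 for Sema5a, 1.62 for Lyz1, 0.95 for Ms4a7 and -1.22 for Arntl.

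The calls of named genes depended on single arrays, while the differences stayed close in size. Without wild_type replicate 1, 2 or 3, 1 probe set passed in each case, and none of the 8 named genes did. Without hIAPP_Tg replicate 4, 5 or 6, 2, 4 and 4 probe sets passed, and Sema5a was among them each time. Over these 6 settings the differences were 4.27 to 4.52 for Sema5a, 2.30 to 2.62 for Lyz1, 2.07 to 2.22 for Snhg18, 1.78 to 1.98 for Ms4a7, 1.53 to 1.63 for Mpeg1, 1.42 to 1.62 for Tyrobp, 1.37 to 1.52 for Pla2g7 and -2.33 to -2.03 for Arntl.

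Genes that did not pass filled the remaining places of the naming rule. Higher in hIAPP_Tg islets, at adjusted p of 0.0517 to 0.0554, were Per3, a clock gene (1.27), the myeloid receptor gene Gpr34 (1.30) and Ms4a6d, a relative of Ms4a7 (1.53). The wild-type levels of Gpr34 (3.93) and Ms4a6d (5.17) lay under the array median of 5.7 and are not known to be above background. Lower were Nfil3, a transcriptional repressor tied to the clock (-1.73, limma adjusted p = 0.0572), and Atp2a2, the calcium pump of the endoplasmic reticulum, for which 5 of 6 probe sets were lower at an unadjusted p under 0.05 (-0.70, limma adjusted p = 0.0566). Farther from the threshold, at adjusted p of 0.0755 to 0.182, were the carboxylesterase gene Ces1d (-1.17), the cyclin gene Ccnh (-0.87), Tex15 (-1.13), Jkamp (-0.80), Plekhh1 (-0.73), the cholinesterase gene Bche (-0.73) and the nucleotide-sugar transporter gene Slc35a2 (-1.23). All 3 probe sets of Ces1d and of Ccnh were lower at an unadjusted p under 0.05, against 1 of 4 for Jkamp and 1 of 3 for Plekhh1 and for Bche, whose probe sets ran up to 0.067. For Slc35a2 it was 1 of 6, and another differed by 0.27 at an unadjusted p under 0.05. With probe sets averaged the differences were -0.20 for Jkamp, -0.24 for Plekhh1, -0.26 for Bche, -0.11 for Slc35a2, -0.44 for Atp2a2, 0.52 for Per3 and 0.71 for Ms4a6d.

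Macrophage and dendritic cell markers rose as a group. All 31 were measured, 25 lay above 0 and 6 below, and their median difference was 0.67 (camera adjusted p = 4.04e-13; adjusted p = 0.449 with an estimated correlation; fry adjusted p = 0.0229), or 0.42 with averaged probe sets. Lyz1, Mpeg1 and Tyrobp passed over all probe sets, and adjusted over the list alone 19 were higher, 4 were lower and 8 did not pass. Besides these 3, the phagosomal marker Cd68 was higher by 1.90, the Fc receptor gene Fcgr3 by 1.57, the complement gene C1qb by 1.37, Adgre1, which encodes the F4/80 antigen, by 1.13 and the cathepsin gene Ctss by 1.13. Csf1r, the receptor for the macrophage growth factor, was higher by 0.67. Lyz2 is on the list too and differed by 2.47 like Lyz1, so the same signal may be counted more than once among the 31. The 4 lower members were those of class II antigen presentation, H2-Ab1 (-0.60), H2-Aa (-0.57), Cd74 (-0.47) and H2-Eb1 (-0.30). None of these 4 passed over all probe sets, and 1 of the 4 H2-Aa probe sets, at the floor, differed by 0.

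Acinar cell markers, the digestive enzyme genes of the exocrine pancreas, fell as a group by a median of -0.97 (28 measured, 26 below 0; camera adjusted p = 1.49e-06; adjusted p = 0.571 with an estimated correlation). No member passed over all probe sets or adjusted over the list alone. The mean over the list was 9.50, 10.54 and 10.86 on the wild-type arrays and 10.34, 8.36 and 9.57 on the hIAPP_Tg arrays. Reg1 differed by -1.10 and Ptf1a, an acinar transcription factor, by -0.27, while Bhlha15 differed by 0.13. The median of the list was -1.48 without wild_type replicate 1, -0.62 without wild_type replicate 3, -1.57 without hIAPP_Tg replicate 4 and -0.33 without hIAPP_Tg replicate 5. With the list mean as a covariate, the median was 0.033, which is no result, since adjusting the list for its own mean brings it near 0. With this covariate, an alternative added after seeing the data, 3 probe sets passed in place of 13, and 8 lists in place of 13. The acinar list is among those lost, for that reason.

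Markers of other cell types did not pass as groups. Endothelial and pericyte markers (28 measured), stellate, fibroblast and matrix genes (34), lymphocyte markers (23) and blood, fat and lymphatic markers (14) had a median difference of 0, duct cell markers (24) one of -0.033 and Schwann and neural cell markers (16) one of 0.12. None of these lists passed camera, and the last had a camera adjusted p of 0.0666. The Schwann and neural list passed with quantile normalization (camera adjusted p = 0.0342), with averaged probe sets (0.0493), with camera on ranks (0.0256), without wild_type replicate 1 (0.0206) and without hIAPP_Tg replicate 6 (0.0442). The stellate and matrix list passed upward without wild_type replicate 1 (camera adjusted p = 0.0357). Single members stood out when adjusted over the list alone. Tgfbi, a matrix protein that macrophages also make, was higher by 1.03 on its brightest probe set and by up to 1.83 on the others, and Lgals3, a galectin of macrophages and duct cells, was higher by 1.73. Abcc9, a potassium channel subunit of pericytes, was higher by 0.57. Lower were Dcdc2a (-1.43, with a second probe set at -0.033) and the lipoprotein lipase gene Lpl (-0.67 on both probe sets).

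Genes of the endocrine cells shifted little. The beta-cell identity list fell by a median of -0.083 (26 measured, 16 below 0 and 6 above; camera adjusted p = 0.00652; adjusted p = 0.513 with an estimated correlation), and 0 members passed adjusted over the list alone. Its largest differences were in Npy (-1.37), Nnat (-0.73) and Trpm5 (-0.67). The glucose transporter gene Slc2a2 differed by -0.37 and Nkx6-1, a beta-cell transcription factor gene, by -0.33. This list did not pass without wild_type replicate 1, without hIAPP_Tg replicate 5 or with the acinar covariate, and its medians in these settings were -0.05, -0.033 and -0.064. With array quality weights, where it passed, the median was -0.031. Genes of hormone processing and granules (30 measured, median 0.033; camera adjusted p = 0.382, or 0.0411 with averaged probe sets) and of the other hormone cells (16 measured, median -0.067; camera adjusted p = 0.384) did not pass. Disallowed and progenitor genes, which mature beta cells keep low, did not pass as a list (29 measured, median 0.033; camera adjusted p = 0.563, or 0.0226 without wild_type replicate 1). Its one member past the threshold adjusted over the list alone was Aldh1a3, a retinaldehyde dehydrogenase, at 7.70 ± 0.53 in hIAPP_Tg and 5.73 ± 0.50 in wild-type islets (log2 difference 1.97, SE 0.34). All 3 of its probe sets were higher at an unadjusted p under 0.05, but the others differed by 0.57 and 0.37 only. The wild-type level of Aldh1a3 lay near the array median of 5.7.

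The autophagy and lysosome list rose, with a median of 0.15 (36 measured, 28 above 0; camera adjusted p = 2.63e-07; adjusted p = 0.513 with an estimated correlation). Adjusted over the list alone 8 members were higher and 0 lower. They were the lysosomal protease genes Ctsd (0.57), Ctsb (0.53), Ctsz (0.53), Lgmn (0.53), Ctsa (0.50) and Ctsl (0.37), Gusb (0.40) and the cholesterol carrier gene Npc2 (0.30). Autophagy genes were not among them, and Ulk1, which starts autophagy, differed by -0.13. Macrophages also express lysosomal genes, and the mean over the macrophage markers was 6.79 to 6.98 on the wild-type and 7.49 to 7.64 on the hIAPP_Tg arrays, so the cells in which this list rose are not known. The oxidative stress list rose by a median of 0.13 (31 measured; camera adjusted p = 0.00325; adjusted p = 0.513 with an estimated correlation). Adjusted over the list alone its members Cybb (0.90) and Cyba (0.73) were higher, subunits of the phagocyte oxidase rather than antioxidant genes, and Nqo1 (-0.70), a quinone reductase gene, was lower. This list did not pass with the acinar covariate, where its median was 0.093, and the median was 0.083 without wild_type replicate 3. The list mean overlapped between the genotypes, at 8.629 to 8.79 on the wild-type and 8.765 to 8.874 on the hIAPP_Tg arrays.

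Among stress genes the heat shock and cytosolic chaperone list rose by a median of 0.27 (24 measured, 21 above 0; camera adjusted p = 0.000467; adjusted p = 0.604 with an estimated correlation). Hspa1a differed by 1.30 and Hspa1b, its near-identical copy, by 1.27, and neither passed. The list mean was 9.433 to 9.8 on the wild-type and 9.617 to 10.292 on the hIAPP_Tg arrays, so the genotypes overlapped. The list did not pass without hIAPP_Tg replicate 6, where its median was 0.13, nor with the acinar covariate, where it was 0.071. Its median was 0.16 without wild_type replicate 3, 0.45 without hIAPP_Tg replicate 4 and 0.17 with averaged probe sets. Immediate early genes rose by a median of 0.27 (29 measured, 22 above 0; camera adjusted p = 4.5e-05; adjusted p = 0.513 with an estimated correlation), with Jun (0.57) and Egr1 (0.57) past the threshold adjusted over the list alone. Their median was 0.17 both without hIAPP_Tg replicate 5 and with the acinar covariate. Genes of protein folding in the endoplasmic reticulum rose by 0.10 (40 measured, 33 above 0; camera adjusted p = 0.00146; adjusted p = 0.524 with an estimated correlation), and 0 members passed adjusted over the list alone. Dnajc10, a disulfide reductase of that compartment, differed by 0.23 and Xbp1, a transcription factor of the unfolded protein response, by 0.20. The mean over this list also overlapped, at 10.915 to 11.12 on the wild-type and 11.11 to 11.13 on the hIAPP_Tg arrays. PERK-ATF4 stress genes did not pass (34 measured, median 0.017; camera adjusted p = 0.475, or 0.0357 without wild_type replicate 1).

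By camera at the preset correlation, lists of metabolism and protein turnover rose by small amounts, and the cell cycle list fell. The list means of single arrays overlapped between the genotypes for proteasome, sterol and cell cycle genes. For cell cycle genes they were 6.461, 6.288 and 6.134 on the wild-type and 6.107, 5.985 and 6.315 on the hIAPP_Tg arrays. Those of mitochondrial respiration and of glycolysis genes did not overlap. Mitochondrial respiration genes rose by a median of 0.13 (44 measured, 39 above 0; camera adjusted p = 1.86e-07; adjusted p = 0.524 with an estimated correlation), and ubiquitin and proteasome genes by 0.13 (37 measured, 32 above 0; camera adjusted p = 1.73e-06; adjusted p = 0.571 with an estimated correlation). Psmb3, a proteasome subunit gene, differed by 0.40 (limma adjusted p = 0.410), and the list median was 0.083 without hIAPP_Tg replicate 5. No member of these lists or of the sterol and cell cycle lists below passed adjusted over the list alone. Sterol and fatty acid synthesis genes rose by 0.17 (29 measured; camera adjusted p = 0.00116; adjusted p = 0.571 with an estimated correlation), although Scd1 differed by -0.53, and this list did not pass without wild_type replicate 1, where its median was 0.10. Without hIAPP_Tg replicate 6 it was 0.083. Glycolysis and hypoxia genes rose by 0.10 (30 measured; camera adjusted p = 0.0144; adjusted p = 0.513 with an estimated correlation), with the glycolytic gene Pgk1 (0.43) past the threshold adjusted over the list alone. They did not pass without hIAPP_Tg replicate 5 or with the acinar covariate, with medians of 0.042 and 0.077, and had a median of 0.058 without wild_type replicate 1. Cell cycle genes fell by a median of -0.13 (41 measured, 28 below 0; camera adjusted p = 0.000232; adjusted p = 0.571 with an estimated correlation). In wild-type islets 15 of the 41 lay under the median level of the array. The list did not pass without wild_type replicate 1 or with array quality weights, where its medians were -0.05 and -0.034. The median was -0.067 without hIAPP_Tg replicate 5, -0.22 without hIAPP_Tg replicate 6 and -0.087 with averaged probe sets.

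**Figure D2:**
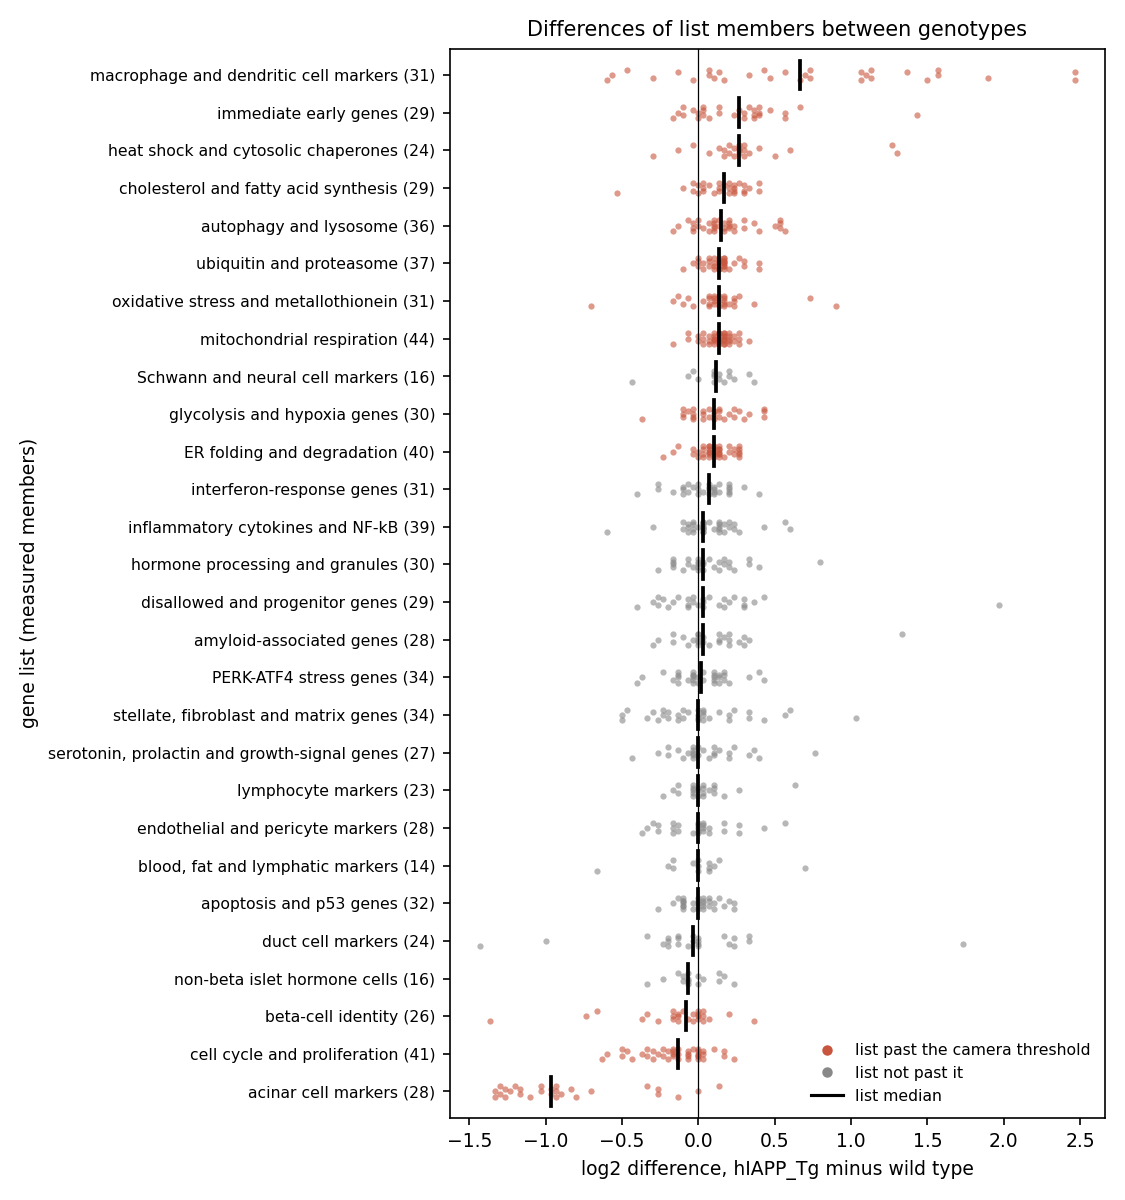
Log2 differences (horizontal axis, hIAPP_Tg minus wild type) of the measured members of 28 gene lists, 1 point per gene, with the list median as a bar and the number of measured members after each name. Macrophage and dendritic cell markers, with a median of 0.67, and acinar cell markers, with one of -0.97, lie farthest from 0.

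Inflammatory cytokine and NF-kB genes (39 measured, median 0.033; camera adjusted p = 0.281) and interferon-response genes (31 measured, median 0.067; camera adjusted p = 0.877) did not pass. Il1r1, the interleukin receptor gene, differed by -0.60 on one probe set and 0.067 on its other. Amyloid-associated genes did not pass as a list (28 measured, median 0.033; camera adjusted p = 0.132, or 0.00656 without wild_type replicate 1). Apoe, an apolipoprotein found in amyloid deposits and made by macrophages, was higher by 1.33 (11.33 ± 0.12 against 10.00 ± 0.36), the 1 member past the threshold adjusted over the list alone. Apoptosis and p53 genes (32 measured) and serotonin, prolactin and growth-signal genes (27 measured) had medians of 0, and of these only Stat5b (-0.43) passed adjusted over the list alone. In all, 13 of the 28 lists passed camera at the preset correlation, 10 upward and 3 downward, 0 with an estimated correlation and 1, the macrophage list, with fry. At the preset correlation, splits of the arrays that mix the genotypes also passed 3 to 13 lists, so these calls alone do not set the genotypes apart. For stellate and matrix, apoptosis and growth-signal genes, none of them past the threshold, the camera direction was down while the mean lay above 0.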

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

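Noise within the rounding step and the acinar covariate were chosen after seeing the data, and the other settings before the data were examined. The count of 13 changed probe sets moved most: 30 with quantile normalization, 51 with a robust prior, 26 with array quality weights, 128 with an ordinary test without moderation (58 higher, 70 lower, 6 of them among the 13), 1 to 4 without single arrays, 3 with the acinar covariate and 53 with rounding noise. All 13 were among the calls with quantile normalization, both filters on dim probe sets, the trend and robust priors and array weights. Leaving out an array also leaves fewer samples. The ordinary test leaves almost no spread to the 286 probe sets with identical rounded values within both genotypes, so even a difference of the rounding step passes there. How many of the 128 calls are of this kind was not counted. The 128 is therefore no count of changed probe sets to set beside the 13. For the other changes the cause was not tested. The 8 named genes past the threshold kept their direction in 128 of 128 comparisons and passed in 80. The ordinary test without moderation is not part of this tally, nor of those of lists and other genes below. With the acinar covariate Sema5a and Snhg18 passed. The list count of 13 became 0 with an estimated correlation, 1 with fry and 8 with the acinar covariate, and 11 to 15 without single arrays. The macrophage list had medians of 0.42 to 0.73 in all settings in which lists were tested, and passed in each of them other than the estimated correlation (median 0.67, adjusted p = 0.449). The brightest Iapp probe set, taken on its own, stayed without a call and differed by 0.011 to 0.067. Signs turned in 17 cases. With the acinar covariate these were the acinar list itself (0.033, set near 0 by its own mean), Derl3 (0.14), Ulk1 (0.015) and Ufd1 (0.047). With probe sets of a gene averaged they were Iapp (-0.017), Ufd1 (0.067), Sox10 (0.011), Srebf2 (0.05) and Nr4a2 (0.044). Hspb1 turned with array weights (0.34). Without single arrays Hspb1 ran from -0.53 to 0.42 and Bhlha15 from -0.23 to 0.42, the stellate and matrix list from -0.092 to 0.11 (the last without wild_type replicate 1, camera adjusted p = 0.0357), Ufd1 from -0.12 to 0.033, Derl3 from -0.52 to 0.033 and Ulk1 from -0.22 to 0.033. None of these genes was past the threshold in any of these settings, and the cause was not tested. Of 247 comparisons of the 13 lists that passed, 210 kept direction and side and 36 lost the call. Of 285 comparisons of the 15 other lists 9 gained a call and 1, given above, passed with its sign turned. Of 2015 comparisons of the 127 named genes not past the threshold 54 gained a call. Of 461 comparisons of the 29 genes named outside the rule 17 did, 8 of them for Lyz2. With quantile normalization the medians of proteasome, sterol, protein folding and glycolysis genes were 0.083, 0.11, 0.056 and 0.047. No paired analysis was possible because the genotypes share no replicate number. Signal near the floor, rounded to steps of 0.1, limits what can be seen of weakly expressed genes.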

Other observations

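The clock gene set below and the tests of this part were chosen after the results were seen, except the test of the acinar markers, that of non-endocrine cells and the count of probe sets over splits of the arrays, which were fixed beforehand. Clock genes differed in opposite directions. Of 18 measured, Cry1 (0.20), Cry2 (0.30) and Rora (-0.033) were placed in neither arm, and the 4 that peak with Arntl were all lower in hIAPP_Tg islets, with a median of -1.52 (Npas2, a partner of Arntl, -1.30; Clock -0.37). The 11 of the opposite phase were all above 0, with a median of 0.97. Among them the output gene Dbp differed by 2.37, Per2 by 1.10, Nr1d2 by 1.07, Tef by 1.03 and Per1 by 0.70. Adjusted over this set alone, itself no independent evidence, 10 were higher and 4 lower. Only Arntl passed over all probe sets.

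The opposite shifts were not confined to Arntl, Nfil3 and Per3, the 3 clock genes that the naming rule had brought up. Without them the score of the one arm minus that of the other still left a gap of 1.29 between the lowest hIAPP_Tg and the highest wild-type array. Chance is not excluded by this, since the set was chosen after the values were seen. A lack of overlap between 3 and 3 arrays is also expected by chance in 10% of cases. Loss of Arntl activity on its own, with all islets taken at the same clock phase, is argued against. It would lower the genes that Arntl activates, and the 10 genes of that arm other than Per3 had a median of 0.93. If the phase differed between the genotypes, these values do not decide on Arntl activity. A difference in the clock phase at which the islets were taken may account for the pattern (gap of 1.78 over both arms). The hour of collection is not given in the sources used here, and a genotype effect on the phase stays open as untested.

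Macrophage markers were higher and acinar markers lower in hIAPP_Tg islets by camera at the preset correlation (adjusted p = 0.449 and 0.571 with an estimated correlation), and none of the 31 macrophage markers is on another list, while 23 reached the median level of the array in wild-type islets. More of all non-endocrine cells is argued against by the mean of the endothelial, fibroblast and lymphocyte scores, which did not rise with the macrophage score. It was 6.66 to 6.88 on the wild-type and 6.72 to 6.79 on the hIAPP_Tg arrays. For the macrophage score minus this mean, the lowest hIAPP_Tg array lay 0.49 above the highest wild-type array. That gap restates macrophage values already seen, and a lack of overlap between 3 and 3 arrays is expected by chance in 10% of cases. The acinar median of -0.97 also points against more of all non-endocrine cells, but with arrays that overlap between the genotypes. The acinar share is argued against as the whole source, since the macrophage median was 0.50 with the acinar covariate and 0.67 without it. The camera adjusted p with the covariate was 4.23e-11, with 1.07e-46 to 0.449 over all alternatives. At the preset correlation it does not measure the spread between mice and adds nothing to this argument. Acinar markers, with a median absolute difference of 0.97 and 92.9% of one sign but a list median of -1.57 to -0.33 without single arrays, may reflect exocrine tissue carried into the preparations. More macrophages and dendritic cells of an unchanged makeup is argued against as the whole source by the class II genes, the highest of which lay at -0.30. These genes were picked after they had been seen to be lower, and RNA of whole islets does not tell which cells they come from. More unchanged macrophages beside less class II RNA from other cells is therefore not excluded. A change in number or state of part of the macrophages with genotype stays open, as a hypothesis that counts of macrophages in islet sections and RNA of sorted macrophages would test.

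Sema5a and Snhg18 are neighbours in the annotation, with 0 measured genes between them. Probes of a single probe set that bind another transcript are argued against as the whole source, since 4 of the 5 probe sets of the pair were higher at an unadjusted p under 0.05. These 4 include the Sema5a probe set near the floor that differed by 1.13. Of random draws of 8 of the 18140 placed genes a share of 0.00324 held neighbours this close (permutation, 100000 draws), but this count was chosen because the pair had been seen, so chance stays undecided. Among the 10 measured genes on each side 4 had an unadjusted p under 0.05, Cct5 (0.40), Cpq (-0.17), Sdc2 (-0.27) and Dnah5 (-0.20), against a median of 2 and a 95th percentile of 4 in random windows, so a wider segment that differs between the genotypes is not decided. An effect at this site, for example of an inserted transgene, may be a candidate explanation, but the insertion site is not given in the sources used here.

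The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The split by genotype gave 13 probe sets (1 split as large) and the highest other 0. For the lists it gave 13, and the splits that mix the genotypes gave 3 to 13 (2 splits as large, counting that by genotype). Camera at the preset correlation thus also passed lists where genotype was not the contrast, so its p-values do not measure the spread between mice. For the macrophage median the split by genotype gave 0.67 and the highest other 0.27 (1 split as large).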
